A study of Mus musculus with 8 samples.

How the data were processed

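RNA was measured by poly-A RNA sequencing in mouse intestinal stromal cells carrying a low level of the receptor Pdgfra. The 8 libraries comprise 3 of stromal cells grown alone (mesenchyme only), 3 of stromal cells grown with wild-type duodenal enteroids, and 2 of stromal cells grown with enteroids carrying a gain-of-function allele of β-catenin (BcatGOF), the transcriptional effector of WNT signalling. Per the labels, 50000 stromal cells were seeded per droplet of basement membrane extract for the cocultures, which lasted 7 days in medium lacking EGF, R-spondin1 and Noggin. GFP-positive cells were sorted with DAPI used to remove dead cells. The sample labels give no seeding number and no culture time for the mesenchyme-only libraries. Whether these match the cocultures is therefore unknown. The design text of the series also names a TGF-β receptor inhibitor, which no sample label mentions, so no sample was assigned to it.

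The authors deposited a table of FPKM values, fragments scaled by transcript length and by library size, for all 8 libraries and 24930 genes. Their second deposited table compares BcatGOF coculture with mesenchyme only and holds only genes past a threshold. In it the authors give log2 fold changes with standard errors. The authors also give a p-value and an adjusted p for each listed gene. The authors' mean normalized count per gene and their test statistic stand beside these. The submitters' processing notes name kallisto 0.46.1, DESeq2 1.40.1 and the build mm9 without saying what each was used for, and how the FPKM values were computed is not given in the sources used here. Genes are named by the symbols of the tables, and no coordinates were used. The tables hold no counts, so the absolute depth of each library is unknown. Relative depth, read from the smallest steps between low values, lay between 0.796 and 1.0 of that of mesenchyme only replicate 1. Column totals ran from 438585 to 598384 FPKM, and 7311 to 7955 genes were at 0 in a library.

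Genes with at least 1 FPKM in at least 2 libraries were kept, which left 12927 genes. Values were transformed as log2 of FPKM plus 1. The added 1 shrinks the log2 fold changes of genes with low FPKM. A linear model with the 3 group means was fitted to the 8 libraries together in limma 3.58.1 (R 4.3.3), with 5 residual degrees of freedom and moderated variances (trend and robust options), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Unless an alternative is named, the p-values given for single genes are two-sided and come from limma. Errors of means are SD over the libraries of a group. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 41 of 43 lists that had at least 3 tested members, and again with a correlation estimated from the residuals. A list is said to have risen or fallen where its adjusted p from camera with the preset correlation was under 0.05. The rotation test fry was run beside camera. Camera with an estimated correlation and fry were run only on the fit without the replicate block. Effects shared by equal replicate numbers therefore stay in their residuals, and no paired version of these 2 tests was run. Members of each list were also adjusted over the list alone, with no correction over the 41 lists. Of the list entries, 14 were not in the table. Plots were drawn with matplotlib 3.10.9 in python 3.11.15.

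The groups, comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule names, for each comparison, up to 12 genes per direction that passed and whose groups did not overlap. Where none passed, it names the 5 genes per direction with the smallest p. It adds the 2 most abundant members, by the mean over all 8 libraries, of a list in which no member passed, and 17 genes for every comparison, of which 1 is not reported here and 16 are named: Pdgfra, Cd81, Grem1, Rspo3, Wnt2b, Bmp4, Foxl1, Tgfb1, Tgfb2, Tgfb3, Acta2, Ctnnb1, Axin2, Gli1, Ptch1 and Epcam. Other genes named were chosen after their values were seen. Those that passed adjusted over the list alone are all named.

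Replicate numbers are shared by the groups. Deviations from the group means correlated between libraries of the same number in different groups at 0.301 to 0.554 (7 pairs) and between libraries of other numbers at -0.483 to 0.208 (14 pairs), and replicate 2 carried Xist in all groups, so the numbers pair the samples. The labels also share a name prefix per replicate number across groups. They do not say what a number or prefix marks, so the pairing rests on these values. A fit with the replicate number as a block was an alternative planned from the start.

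The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean of 5 FPKM, quantile normalization, trimmed-mean scaling, the replicate block as a fixed or random effect, fits of 2 groups alone, variances without trend and robust options, sample quality weights, and leaving out each library in turn. Omitting small RNA genes, omitting wild-type replicate 3 with BcatGOF replicate 2, and the block without BcatGOF replicate 1 were added after seeing the data. Omitting wild-type replicate 3 with BcatGOF replicate 2 leaves BcatGOF replicate 1 alone in its group. It cannot separate epithelial content from the loss of BcatGOF replicate 2. Quantile normalization and trimmed-mean scaling gave a median log2 fold change over all genes between 0 and 0.0135, so changes are not given relative to it. Count models were not run because the tables hold no counts.

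The procedure was tested on simulated data with changes planted in 200 genes, using the variances seen here. Noise was drawn independently for each gene and library, without correlation between genes or effects shared by replicate numbers. The shares called therefore need not hold for the real data. Planted log2 changes of 1, 2 and 3 were called in 38.8%, 94.0% and 95.5% of the genes for wild-type coculture against mesenchyme only. The shares were 31.3%, 86.6% and 93.9% for BcatGOF coculture against mesenchyme only and 26.9%, 86.6% and 92.4% for BcatGOF against wild-type coculture, with 8 or 9 unchanged genes called. Unchanged data that kept the correlation between genes seen in the residuals were also drawn 100 times, to see how many lists camera calls without any effect. The libraries of a draw are independent, so effects shared by equal replicate numbers are not in these draws. The residuals come from the fit without the replicate block. Variation that goes with the replicate number therefore enters the draws as noise of unpaired libraries. In wild-type coculture against mesenchyme only each number is in both groups, so the count of draws with as many lists can be too high there.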

Results

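Transcripts of Pdgfra-low intestinal stromal cells were measured after culture alone (3 libraries) and after 7 days with wild-type (3 libraries) or BcatGOF enteroids (2 libraries). Totals per library ran from 438585 to 598384 FPKM, and the number of reads behind them is unknown. Saa3, an acute phase protein, was the most abundant transcript in all 8 libraries and held 1.31% to 7.46% of the FPKM. Libraries numbered 2 carried Xist at 27.2 to 34.9 FPKM, and libraries numbered 1 and 3 carried the Y-linked Ddx3y at 15.8 to 20.8 FPKM, so the replicate number went with sex. The first principal component of the tested genes held 40.3% of the variance. It placed BcatGOF replicate 2 at 63.6 and the other 7 libraries between -38.9 and 25.4, with BcatGOF replicate 1 at -19.9. Krt8, a keratin of epithelia, was at 0.0688 ± 0.0153 FPKM (SD, n = 3) in cells grown alone. In the GFP-positive cells sorted from the wild-type cocultures it was at 3.86, 0.813 and 35.4 FPKM, and in the BcatGOF cocultures at 7.27 and 38.5 FPKM.

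The comparison of wild-type coculture with mesenchyme only asks what healthy enteroids do to the stromal cells. Gli1, a target of Hedgehog signalling, was at 3.53 ± 1.43 FPKM (SD, n = 3) in coculture against 0.327 ± 0.198 FPKM (n = 3) in cells grown alone. Inhba, which encodes the activin A subunit, was at 39.6 ± 10.1 against 10.3 ± 2.9 FPKM, and Col5a3, a fibrillar collagen, at 61.4 ± 1.81 against 23.7 ± 5.98 FPKM. Plin1, a lipid droplet protein, was at 0.398 ± 0.404 against 4.81 ± 2.45 FPKM, and Wnt2b, a canonical WNT ligand, at 0.627 ± 0.375 against 4.31 ± 3.16 FPKM. These 5 genes passed adjusted over the list alone and not over all genes. Snora15, a small nucleolar RNA, was listed at 9.74 ± 1.2 FPKM in cells grown alone and at 0 in all 3 cocultures (adjusted p = 0.000549, limma), lower in 3 of 3 libraries.

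Snora15 was the only gene of 12927 to pass over all genes in limma, with 0 higher and 1 lower. At an unadjusted p under 0.05 there were 634 genes, 1334 with the replicate block and 1419 with the block as a random effect, where chance alone gives 646. Small RNA genes were taken by the start of their symbols, which also matches host genes such as those named Snhg. Of the 349 genes so taken and tested, 46 were above 0 in exactly 3 of the 8 libraries, and without them no gene passed. With the replicate block Moxd1, a monooxygenase-like protein, also passed, at 15.6 ± 6.69 FPKM in coculture and 1.36 ± 1.09 FPKM in cells grown alone (log2 fold change 2.85, adjusted p = 0.0137 with the block, limma).

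The list of hypoxia and glycolysis genes rose, with 26 of 26 tested members higher and a median log2 fold change of 0.68 (adjusted p = 7.45e-14 in camera, and adjusted p = 0.394 with an estimated correlation). Over the mesenchyme-only library of the same number the list's mean rose by 1.21, 0.12 and 0.88 in replicates 1, 2 and 3. Its most abundant members, the glycolytic enzymes Gapdh and Aldoa, had log2 fold changes of 0.64 (SE 0.44) and 0.58 (SE 0.35), and Vegfa, which drives vessel growth, was at 290.1 ± 23.3 against 140.2 ± 22.4 FPKM. In the same comparison 16 of 18 epithelial markers were higher, by a median of 0.92 on the log2 scale (adjusted p = 1.47e-05, and adjusted p = 0.573 with an estimated correlation). Its most abundant members were Krt19, at a log2 fold change of 1.7 (SE 0.91), and Smoc2, at 0.81 (SE 0.60) and 203 FPKM in cells grown alone. The mean log2 value of the epithelial list above that in cells grown alone was 0.44 in wild-type replicate 1, 0.21 in replicate 2 and 2.27 in replicate 3.

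The TGF-β response list rose, with 20 of 24 members higher and a median of 0.55 (adjusted p = 9.46e-08, and adjusted p = 0.384 with an estimated correlation). In it Pmepa1 (1.38, SE 0.25), Postn (1.44, SE 0.38), Lox (1.13, SE 0.32), Snai1 (0.99, SE 0.24) and Skil (0.68, SE 0.20) passed adjusted over the list alone, and with the replicate block 11 members did. Its most abundant members, Col1a1 and Fn1, had log2 fold changes of 1.1 (SE 0.52) and 0.73 (SE 0.28). The list of collagens and cross-linking enzymes rose, with 22 of 24 members higher and a median of 0.57 (adjusted p = 2.38e-08, and adjusted p = 0.394 with an estimated correlation). Col5a3 passed adjusted over the list alone (1.36, SE 0.19), while Col3a1, its most abundant member over all 8 libraries, was at -0.037 (SE 0.62). The list of cancer-associated fibroblast markers rose, with 12 of 15 members higher and a median of 0.36 (adjusted p = 9.52e-04, and adjusted p = 0.359 with an estimated correlation). Inhba (1.84, SE 0.27) and Postn passed in it adjusted over the list alone, and its most abundant members Spon2 and Il11 had log2 fold changes of 0.90 (SE 0.52) and 3.22 (SE 1.25). The 3 mesothelial markers rose by a median of 1.24 (adjusted p = 0.0405, adjusted p = 0.443 with an estimated correlation, and 0.0639 with the replicate block), Msln at 1.24, Wt1 at 1.11 (SE 0.87) and Krt19, which is also in the epithelial list, at 1.7. Their mean log2 value above that in cells grown alone was 0.55, 0.65 and 2.85 in wild-type replicates 1, 2 and 3, highest in the same library as the epithelial list.

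Interferon-stimulated genes fell, with 26 of 26 members lower and a median of -0.47 (adjusted p = 3.13e-11, and adjusted p = 0.359 with an estimated correlation), and its most abundant members B2m and Ifi27 had log2 fold changes of -0.33 (SE 0.33) and -0.19 (SE 0.26). Immediate early and dissociation genes fell, with 22 of 24 lower and a median of -0.66 (adjusted p = 4.20e-08, and adjusted p = 0.394 with an estimated correlation). Junb and Ier3 had log2 fold changes of -0.67 (SE 0.45) and -0.033 (SE 0.63). Fatty acid and adipogenic genes fell, with 12 of 16 lower and a median of -0.26 (adjusted p = 6.19e-04, and adjusted p = 0.384 with an estimated correlation). Of these, the adipocyte regulators Pparg (-1.64, SE 0.41) and Cebpa (-1.62, SE 0.40), with Plin1 (-2.02, SE 0.32), passed adjusted over the list alone, and the abundant members Apoe and Cebpb had log2 fold changes of -1.91 (SE 0.92) and 0.20 (SE 0.48). Immune cell markers fell, with 8 of 9 lower and a median of -0.67 (adjusted p = 0.00188, and adjusted p = 0.573 with an estimated correlation), Lyz2 at -0.67 (SE 0.59) and Cd14 at -0.80 (SE 0.63). Trophocyte and adventitial fibroblast markers fell, with 11 of 16 lower and a median of -0.63 (adjusted p = 0.0152, and adjusted p = 0.415 with an estimated correlation). Grem1, an antagonist of BMP signalling, had a log2 fold change of -0.63 (SE 0.34), and C3, a complement protein, one of -1.26 (SE 0.60).

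The list of WNT ligands and R-spondins had members on both sides and its median was 0.18 (adjusted p = 0.772). Wnt5a (1.27, SE 0.35) and Wnt11 (1.89, SE 0.57), ligands of noncanonical WNT signalling, were higher, and Wnt2b (-1.57, SE 0.51) and Rspo2 (-1.42, SE 0.35), which amplifies WNT signalling, were lower, each passing adjusted over the list alone. Rspo3 had a log2 fold change of -0.61 (SE 0.35). Among Hedgehog targets only Gli1 (1.73, SE 0.31) passed adjusted over the list alone (adjusted p = 0.0073), with Ptch1 at 0.45 (SE 0.22) and Foxl1 at 0.74 (SE 0.28). In the list of interstitial cells of Cajal, Gucy1b1 (-1.02, SE 0.33) and Prkg1 (-1.09, SE 0.35), both of cyclic GMP signalling, were lower and passed adjusted over the list alone. Tgfb1 was at 122 ± 35.1 against 57.2 ± 12.6 FPKM (adjusted p = 0.838, limma). Of the other genes named in every comparison, none passed. Pdgfra had a log2 fold change of -0.21, Cd81 0.089, Bmp4 -0.48, Tgfb2 -0.63, Tgfb3 0.43, Acta2 -1.03, Ctnnb1 0.35, Axin2 -0.26 and Epcam 1.08. Epcam was at 0.30, 0.16 and 5.78 FPKM in wild-type replicates 1, 2 and 3 and at most 0.058 FPKM in cells grown alone. The added 1 FPKM shrinks its log2 fold change.

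Camera called 6 lists up and 5 down. It called 0 with an estimated correlation, and fry called 0 (lowest adjusted p = 0.389). Both were run without the replicate block, so they do not show whether lists would pass in a paired test of this kind. In simulated unchanged data camera called a median of 13 lists, and 65 of 100 draws gave at least the 11 found here. The draws hold replicate effects as noise of unpaired libraries, so this share does not settle what the paired libraries would give by chance. The gene count was 9 without BcatGOF replicate 2, 7 without BcatGOF replicate 1 and 9 without wild-type replicate 3 and BcatGOF replicate 2.

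**Figure D1:**
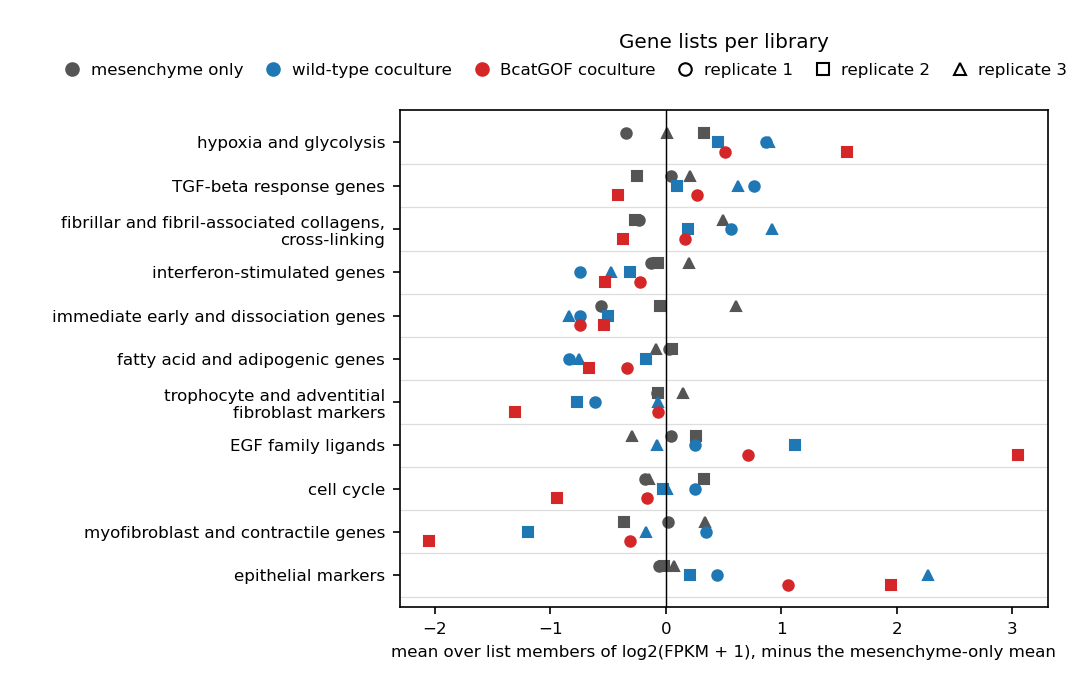
Mean over the members of 11 gene lists of log2(FPKM + 1), minus the mesenchyme-only mean, for each library (colour, group; shape, replicate number). In the hypoxia and glycolysis list the cocultures sit between 0.45 and 1.57 and the cells grown alone between -0.34 and 0.33. BcatGOF replicate 2 is highest, and wild-type replicate 2 (0.45) lies close to mesenchyme-only replicate 2 (0.33).

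The comparison of BcatGOF coculture with mesenchyme only asks how enteroids with active β-catenin change the stromal cells. Inhba was at 34.3 and 50.1 FPKM in the 2 libraries, against 10.3 ± 2.9 FPKM (SD, n = 3) in cells grown alone. Gli1 was at 4.22 and 2.18 against 0.327 ± 0.198 FPKM, and Nrg1, a ligand of ErbB receptors, at 48.5 and 116 against 23.1 ± 8.29 FPKM. Vegfa was at 254 and 659.5 against 140.2 ± 22.4 FPKM, and Snai1, a transcription factor of mesenchymal cells, at 109 and 197 against 66.5 ± 7.05 FPKM. These 5 genes passed adjusted over the list alone and not over all genes. Snora15 was listed at 9.74 ± 1.2 FPKM in cells grown alone and at 0 in both libraries (adjusted p = 0.00129, limma), lower in 2 of 2 libraries.

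Snora15 was again the 1 gene lower of 12927, and 0 were higher in limma. At an unadjusted p under 0.05 there were 711 genes, 1014 with the replicate block and 1296 with the block as a random effect, where chance alone gives 646. The 2 libraries differed: without BcatGOF replicate 1, 105 genes were higher and 93 lower of 12814, with the lone sample assumed to vary like the other groups, and without wild-type replicate 2, 1 was higher and 1 lower. Among those 105 and 93 were the cytokine Il11, at a log2 fold change of 7.23 (adjusted p = 0.04), the enkephalin precursor Penk at 6.34, the matrix protease Mmp9 at 4.57, the EGF receptor ligand Btc at 3.42 and Vegfa at 2.24. Lower were Ifi27l2a at -6.31, the growth factor Ptn at -5.67, Serpina3n at -4.91, Chodl at -3.66, Chl1 at -3.43, Abi3bp at -3.26, the adhesion molecule Vcam1 at -2.62, the WNT target Nkd1 at -1.99 and the proliferation marker Mki67 at -1.43. Il11 was at 85.8 FPKM in BcatGOF replicate 1 and 2587 FPKM in replicate 2, against 20.5 ± 17 FPKM in cells grown alone, and Mmp9 at 198 and 3223 against 142 ± 54.6 FPKM. All of these genes but Il11, Mmp9 and Vegfa were chosen after their values were seen.

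The hypoxia and glycolysis list rose, with 26 of 26 members higher and a median of 0.92 (adjusted p = 5.42e-19 in camera, and adjusted p = 0.564 with an estimated correlation). Without BcatGOF replicate 1 the median was 1.51. The list's mean over that in the mesenchyme-only library of the same number was 0.86 in replicate 1 and 1.24 in replicate 2. Vegfa (1.55, SE 0.38), the hexokinases Hk1 (0.77, SE 0.21) and Hk2 (0.70, SE 0.18), and Ankrd37 (1.97, SE 0.51) passed adjusted over the list alone, and Gapdh and Aldoa had log2 fold changes of 0.87 (SE 0.49) and 0.88 (SE 0.39). With the replicate block Vegfa and Hk2 stayed under 0.05 over the list (0.026 for each) and Hk1 and Ankrd37 were at 0.051. The oxygen sensor Egln3 of the same list had one of 1.46 (SE 0.49). Epithelial markers rose as well, with 15 of 18 higher and a median of 1.41 (adjusted p = 8.82e-09, and adjusted p = 0.564 with an estimated correlation), with Krt19 at 2.93 (SE 1.02), Krt8 at 4.08 (SE 1.16) and Smoc2 at -0.065 (SE 0.67). The list's mean log2 value above that in cells grown alone was 1.06 in replicate 1 and 1.95 in replicate 2. EGF family ligands rose, with 6 of 6 members higher and a median of 1.98 (adjusted p = 7.17e-06 in camera, and adjusted p = 0.564 with an estimated correlation). Their median was 3.42 without BcatGOF replicate 1. Over the mesenchyme-only library of the same number their mean was 0.67 in replicate 1 and 2.8 in replicate 2. Nrg1 (1.72, SE 0.45) passed adjusted over the list alone. Ereg was at 313 and 2058 against 183 ± 39.5 FPKM, and Areg at 27.6 and 368 against 14.1 ± 4.62 FPKM. BMP and SMAD target genes rose, with 12 of 12 higher and a median of 0.58 (adjusted p = 0.00157, and adjusted p = 0.565 with an estimated correlation), Id1 at 0.74 (SE 0.79) and Id3 at 0.11 (SE 0.53). The mean of this list over that in the mesenchyme-only library of the same number was -0.22 in replicate 1 and 1.08 in replicate 2. Oxidative phosphorylation genes rose by a median of 0.18 with 25 of 29 higher (adjusted p = 0.0390, adjusted p = 0.744 with an estimated correlation, and 0.650 with the replicate block), with Cox6a1 at 0.15 and Cox6b1 at 0.18. Over the mesenchyme-only library of the same number the mean of this list was -0.067 in replicate 1 and 0.035 in replicate 2, so little of the rise was seen within pairs. Without BcatGOF replicate 2 the mean of this list turned from 0.19 to -0.10.

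Cell cycle genes fell, with 28 of 31 lower and a median of -0.64 (adjusted p = 4.36e-10, and adjusted p = 0.564 with an estimated correlation). Its most abundant members Pcna and Mcm7 had log2 fold changes of -0.12 (SE 0.30) and -0.36 (SE 0.26). Myofibroblast and contractile genes fell, with 14 of 15 lower and a median of -1.32 (adjusted p = 1.18e-05, and adjusted p = 0.564 with an estimated correlation). Acta2, smooth muscle actin, was at 375 and 22.2 FPKM against 524 ± 172 FPKM, and Tpm1 had a log2 fold change of -0.55 (SE 0.36). YAP/TAZ targets fell, with 13 of 14 lower and a median of -0.60 (adjusted p = 0.00157, and adjusted p = 0.565 with an estimated correlation), F3 at -1.77 (SE 0.65) and Ccn1 at -1.2 (SE 0.50). Immediate early genes fell by a median of -0.65 with 22 of 24 lower (adjusted p = 2.63e-05, and adjusted p = 0.564 with an estimated correlation), although Ier3 was at 1.27 (SE 0.71), with Junb at -0.52 (SE 0.50). Interferon-stimulated genes fell by a median of -0.33 with 22 of 26 lower (adjusted p = 9.32e-05, and adjusted p = 0.564 with an estimated correlation), with B2m at -0.50 (SE 0.37) and Ifi27 at -0.24 (SE 0.29). Trophocyte markers fell by a median of -0.74 with 13 of 16 lower (adjusted p = 0.00568, and adjusted p = 0.564 with an estimated correlation), with Grem1 at -0.40 (SE 0.39) and C3 at -1.02 (SE 0.68). Over the mesenchyme-only library of the same number, list means were 0.021 in replicate 1 and -1.27 in replicate 2 for cell cycle genes, and 0.0065 and -1.24 for trophocyte markers. They were -0.33 and -1.69 for myofibroblast genes, and -0.14 and -0.70 for YAP/TAZ targets.

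Complement and acute phase genes fell by a median of -0.38 (9 of 14 lower, adjusted p = 0.0258, and adjusted p = 0.565 with an estimated correlation), and without BcatGOF replicate 1 the adjusted p was 0.0934. Saa3 had a log2 fold change of 0.089 (SE 1.06) and Lcn2 one of 1.26 (SE 1.63). Fatty acid and adipogenic genes fell by a median of -0.35 (12 of 16 lower, adjusted p = 0.0258, adjusted p = 0.564 with an estimated correlation, and 0.0934 without replicate 1), with Apoe at -2.5 (SE 1.03) and Cebpb at -0.03 (SE 0.54). Cholesterol biosynthesis genes fell by a median of -0.18 (17 of 23 lower, adjusted p = 0.0258, adjusted p = 0.744 with an estimated correlation, and 2.26e-08 with the replicate block), with Fdps at 0.044 (SE 0.48) and Srebf2 at -0.055 (SE 0.18). The median of the cholesterol list was -0.070 without BcatGOF replicate 1. Over the mesenchyme-only library of the same number its mean was -0.22 in replicate 1 and -0.41 in replicate 2. Other matrix glycoproteins and proteoglycans fell by a median of -0.35 (16 of 26 lower, adjusted p = 0.0390, adjusted p = 0.658 with an estimated correlation, and 0.263 with the replicate block), with Dcn at 0.40 (SE 0.36) and Bgn at -0.32 (SE 0.31).

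In lists that did not pass, Inhba (1.94, SE 0.30), Skil (0.96, SE 0.22), Snai1 (1.13, SE 0.27), Gli1 (1.63, SE 0.34) and the macrophage elastase Mmp12 (2.43, SE 0.50) passed adjusted over the list alone. Of the genes named in every comparison none passed over all genes. Tgfb1 was at 151 ± 76.3 against 57.2 ± 12.6 FPKM (adjusted p = 0.894, limma), and Bmp4 at 14.5 ± 2.34 against 26.2 ± 1.1 FPKM (adjusted p = 0.894, limma). Log2 fold changes were -0.57 for Pdgfra, 0.12 for Cd81, -0.70 for Rspo3, -1.19 for Wnt2b, 0.75 for Foxl1, -0.69 for Tgfb2, -0.67 for Tgfb3, 0.30 for Ctnnb1, -0.80 for Axin2, 0.61 for Ptch1 and 2.05 for Epcam.

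Camera called 5 lists up and 10 down. It called 0 with an estimated correlation, and fry called 0 (lowest adjusted p = 0.533), both without the replicate block. In simulated unchanged data camera called a median of 12 lists, and 33 of 100 draws gave at least the 15 found here. The limit of such draws given above holds here too. Leaving out wild-type replicate 3 and BcatGOF replicate 2 leaves BcatGOF replicate 1 alone in its group. That setting therefore cannot tell epithelial content from the loss of BcatGOF replicate 2. Without wild-type replicate 3 and BcatGOF replicate 2, the libraries with the highest epithelial values, 8 of the 15 list calls kept their direction and threshold. Of the others, the adjusted p was 0.902 for BMP and SMAD targets, 0.805 for YAP/TAZ targets, 0.535 for trophocyte markers, 0.157 for myofibroblast genes, 0.0847 for fatty acid genes and 0.889 for other matrix glycoproteins, and oxidative phosphorylation turned direction.

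**Figure D2:**
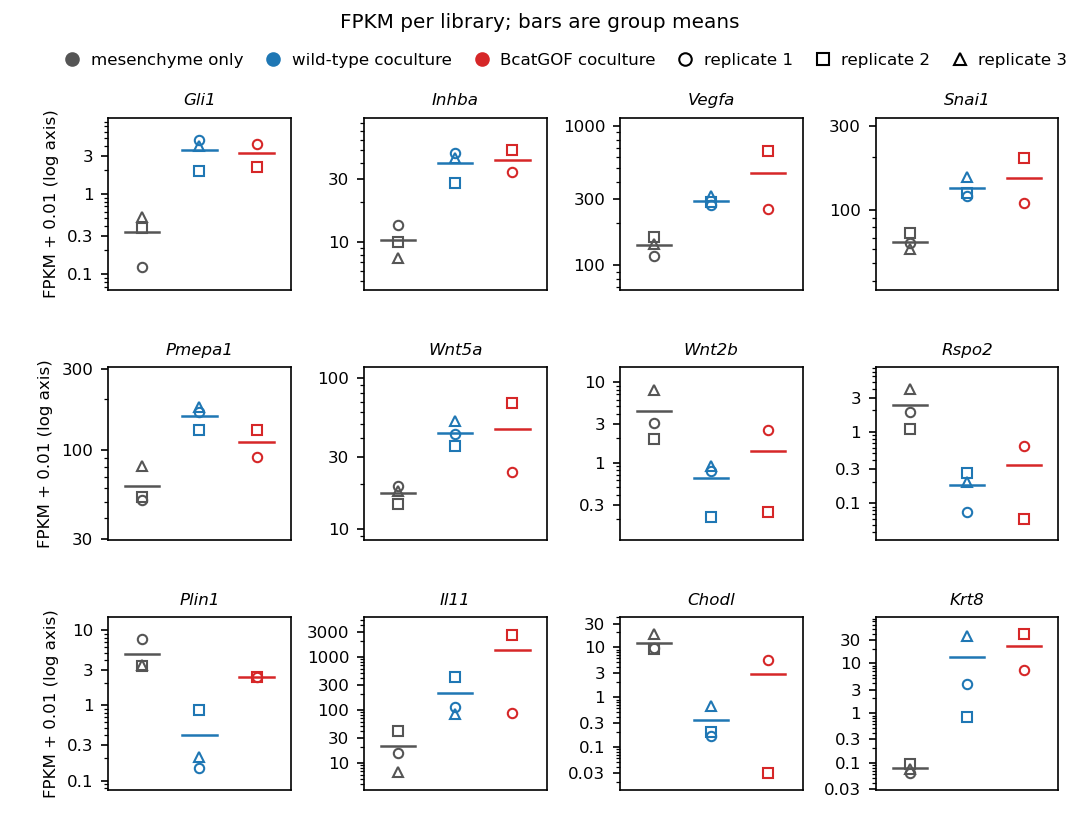
FPKM per library on a log axis for 12 genes, with bars at the group means and shapes for the replicate number (0.01 is added for display). Gli1 and Inhba are higher in all 5 cocultures than in all 3 libraries of cells grown alone, whereas Il11 and Chodl set BcatGOF replicate 2 apart from replicate 1.

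The authors' deposited table for the same comparison lists 2184 genes, 925 higher and 1259 lower in BcatGOF coculture, with adjusted p-values up to 0.015. At an adjusted p under 0.01 the authors' deposited table holds 832 higher and 1133 lower. From the authors' deposited table, 1955 genes were tested here, 99.7% had the same sign as the fit of both BcatGOF libraries, and 0 passed in limma. In the authors' deposited table Il11 has a log2 fold change of 6.8, Mmp9 of 4.44 and Vegfa of 2.34, while Serpina3n has one of -4.53 and Mki67 one of -2.99. Of its list members, the authors' deposited table holds 24 of the 26 hypoxia and glycolysis genes as higher and 25 of the 31 cell cycle genes as lower. It also holds all 6 EGF family ligands as higher. Fold changes of 1900 genes with a mean normalized count above 50 in the authors' deposited table lay within 0.5 log2 of BcatGOF replicate 2 over the mesenchyme-only mean for 86.9% of genes, of replicate 1 for 2.89%, and of the mean of both for 24.2%. Of the 198 genes that passed here without BcatGOF replicate 1, 192 are in the authors' deposited table.

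**Figure D3:**
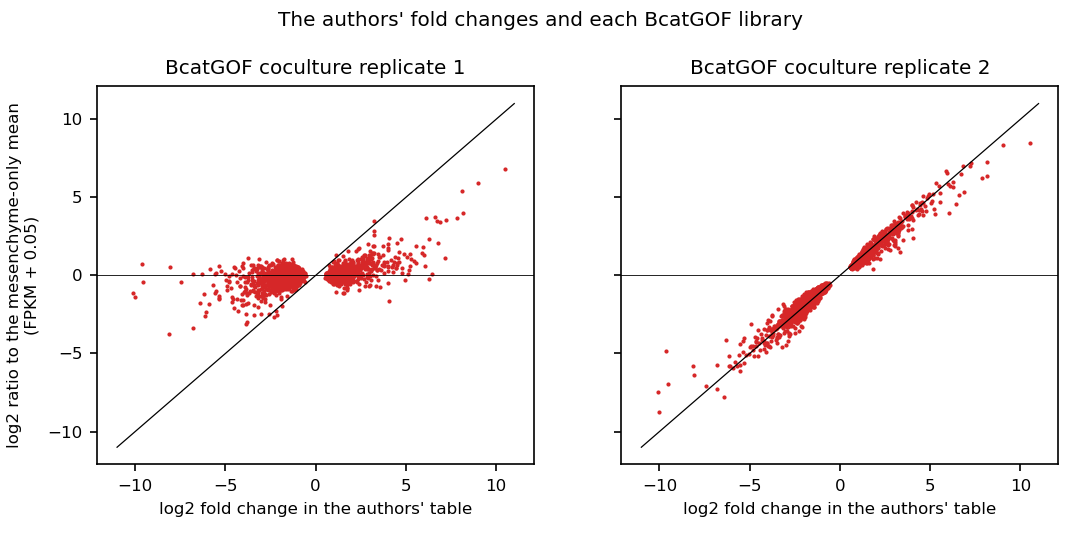
Log2 fold change in the authors' deposited table (x axis) against the log2 ratio of each BcatGOF library to the mesenchyme-only mean (y axis, FPKM + 0.05) for 1858 tested genes, with the line of equal values. Points for BcatGOF replicate 2 follow the line, and points for replicate 1 lie closer to 0.

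The comparison of BcatGOF with wild-type coculture asks what the β-catenin allele of the enteroid adds. Asns, which makes asparagine, was at 43.5 and 53.3 FPKM in BcatGOF coculture against 87.4 ± 5.53 FPKM (SD, n = 3) in wild-type coculture. The serine synthesis enzymes Phgdh and Psat1 were at 20 ± 14.5 and 20.4 ± 12 FPKM (SD, n = 2) against 46.7 ± 7.23 and 49.8 ± 13.8 FPKM, and Chac1, which degrades glutathione, at 4.16 ± 1.6 against 10.9 ± 0.925 FPKM. These 4 genes were lower and passed adjusted over the list alone (adjusted p from 0.026 to 0.046, limma) in the list of unfolded protein and integrated stress response genes, whose median was 0.11, mean -0.10 and test direction down (adjusted p = 0.781). With the replicate block Asns and Chac1 stayed under 0.05 over the list (0.043 for each) and Psat1 and Phgdh did not (0.091 for each), and without BcatGOF replicate 1 Psat1 and Phgdh did and Asns and Chac1 did not (0.070 for each). No gene passed over all genes in limma, and 373 had an unadjusted p under 0.05 (650 with the replicate block and 772 with the block as a random effect), where chance alone gives 646.

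The genes with the smallest p did not pass. On the lower side they include Mthfd2, at 19 ± 0.705 against 42.9 ± 1.43 FPKM, and Shmt2, at 37.6 ± 0.725 against 68.8 ± 8.49 FPKM, both of mitochondrial one-carbon metabolism, and Gpt2, a transaminase, at 4.08 ± 0.484 against 8.8 ± 0.621 FPKM (adjusted p = 1 for each, limma). Snord68 (7.47 ± 3.45 FPKM) and Mir7024 (2.65 ± 1.44 FPKM) had values in wild-type coculture and were listed at 0 in both BcatGOF libraries. On the higher side were Mir7669 (3.36 ± 2.21 FPKM), Mir1964 (4.47 ± 0.868 FPKM), Mir6998 (1.45 ± 0.122 FPKM), Mir320 (1.29 ± 0.0455 FPKM) and Mir7682 (4.42 ± 3.93 FPKM). These had values in BcatGOF coculture and were listed at 0 in all 3 wild-type libraries. Whether such values in poly-A libraries come from the small RNAs themselves was not tested.

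Cell cycle genes were lower in BcatGOF than in wild-type coculture, 31 of 31 members (adjusted p = 4.57e-17 in camera, and adjusted p = 0.504 with an estimated correlation), with Pcna at -0.15 (SE 0.30) and Mcm7 at -0.49 (SE 0.26). Collagens were lower for 21 of 24 members (adjusted p = 2.64e-08, and adjusted p = 0.504 with an estimated correlation), with Col1a1 at -1.4 (SE 0.58) and Col3a1 at -0.89 (SE 0.69). TGF-β response genes were lower for 19 of 24 (adjusted p = 2.73e-05, and adjusted p = 0.504 with an estimated correlation), with Fn1 at -0.19 (SE 0.31). Myofibroblast genes were lower for 15 of 15 (adjusted p = 1.30e-04, and adjusted p = 0.629 with an estimated correlation), with Acta2 at -1.4 (SE 1.21) and Tpm1 at -0.49 (SE 0.36). Ribosomal protein genes were lower for 34 of 34 (adjusted p = 3.56e-05, adjusted p = 0.713 with an estimated correlation, and 1.2e-14 with the replicate block), with Rplp1 at -0.50 (SE 0.37) and Rps2 at -0.32 (SE 0.30). The median of this list was -0.027 without BcatGOF replicate 1. Between libraries of the same number its mean differed by -0.50 in replicate 1 and -0.20 in replicate 2. EGF family ligands were higher for 6 of 6 (adjusted p = 6.84e-05, and adjusted p = 0.504 with an estimated correlation), with Ereg at 1.99 (SE 0.81) and Areg at 2.27 (SE 1.2). Hypoxia and glycolysis genes were higher for 25 of 26 (adjusted p = 0.00116, and adjusted p = 0.713 with an estimated correlation), with Gapdh at 0.23 (SE 0.49) and Aldoa at 0.30 (SE 0.39). BMP and SMAD targets were higher for 10 of 12 (adjusted p = 0.00129, and adjusted p = 0.629 with an estimated correlation), with Id1 at 0.83 (SE 0.79) and Id3 at 0.42 (SE 0.53). Canonical WNT targets were lower for 7 of 9 (adjusted p = 0.0283, and adjusted p = 0.629 with an estimated correlation), with Nkd2 at -1.6 (SE 0.48) and Ccnd1 at 0.11 (SE 0.59). Epithelial markers were higher for 14 of 18 (adjusted p = 0.00526, and adjusted p = 0.713 with an estimated correlation), with Krt19 at 1.23 (SE 1.02) and Smoc2 at -0.87 (SE 0.67).

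Other matrix glycoproteins were lower for 20 of 26 (adjusted p = 3.44e-04, and adjusted p = 0.619 with an estimated correlation), with Dcn at 0.30 (SE 0.36) and Bgn at -0.71 (SE 0.31). Fibroblast activation markers were lower for 11 of 15 (adjusted p = 0.00879, and adjusted p = 0.504 with an estimated correlation), with Spon2 at -0.24 (SE 0.58) and Il11 at 1.56 (SE 1.4). WNT ligands and R-spondins were lower for 8 of 10 (adjusted p = 0.0216, adjusted p = 0.629 with an estimated correlation, 0.116 with the replicate block and 0.314 without BcatGOF replicate 1), with Rspo1 at -0.46 (SE 0.40) and Rspo3 at -0.09 (SE 0.40). NRF2 and metallothionein genes were higher for 10 of 12 (adjusted p = 0.00244, and adjusted p = 0.619 with an estimated correlation), with Mt1 at 0.26 (SE 0.49) and Prdx1 at 0.29 (SE 0.39). FGF, HGF and IGF ligands were higher for 8 of 13 (adjusted p = 0.0140, adjusted p = 0.504 with an estimated correlation, and 0.145 without BcatGOF replicate 1), with Vegfa at 0.50 (SE 0.38) and Igf1 at -0.80 (SE 0.77). Interferon-stimulated genes were higher for 19 of 26 (adjusted p = 0.0492, adjusted p = 0.685 with an estimated correlation, and 0.914 without BcatGOF replicate 1), with B2m at -0.17 (SE 0.37) and Ifi27 at -0.049 (SE 0.29). Between BcatGOF and wild-type libraries of the same number, list means differed by -0.14 in replicate 1 and 0.79 in replicate 2 for BMP and SMAD targets, and by -0.35 and 1.12 for hypoxia and glycolysis. They differed by 0.095 and -0.75 for WNT ligands, and by 0.51 and -0.22 for interferon-stimulated genes.

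Of the genes named in every comparison none passed, and Tgfb3 was at 19.9 ± 7.11 against 43.8 ± 11.9 FPKM (adjusted p = 1, limma). Log2 fold changes were -0.36 for Pdgfra, 0.033 for Cd81, 0.23 for Grem1, 0.38 for Wnt2b, -0.34 for Bmp4, 0.0066 for Foxl1, 0.25 for Tgfb1, -0.052 for Tgfb2, -0.04 for Ctnnb1, -0.54 for Axin2, -0.096 for Gli1, 0.16 for Ptch1 and 0.98 for Epcam. Camera called 7 lists up and 9 down. It called 0 with an estimated correlation, and fry called 0 (lowest adjusted p = 0.572), both without the replicate block. In simulated unchanged data a median of 13 lists was called, with at least 16 in 24 of 100 draws. Leaving out wild-type replicate 3 and BcatGOF replicate 2 leaves BcatGOF replicate 1 alone in its group. That setting cannot tell epithelial content from the loss of BcatGOF replicate 2. The list count was 8 without BcatGOF replicate 2 and 7 without wild-type replicate 3 and BcatGOF replicate 2, where 4 of the 16 list calls kept their direction and threshold. Without that pair the hypoxia, BMP and SMAD target, EGF family and myofibroblast lists turned direction, and the adjusted p was 0.116 for collagens, 0.0968 for TGF-β response genes, 0.698 for other matrix glycoproteins, 0.463 for fibroblast activation markers, 0.934 for canonical WNT targets, 0.206 for NRF2 genes, 0.156 for WNT ligands and 0.141 for FGF, HGF and IGF ligands.

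The effects of both cocultures against cells grown alone correlated across genes at r = 0.661 with a covariance of 0.124, where genes are not independent replicates. Both comparisons share the 3 mesenchyme-only libraries, and simulated unchanged groups against shared controls gave a mean r of 0.388 (from -0.721 to 0.983) and a mean covariance of 0.0546 (at most 0.264). The draws treat the libraries as independent and do not keep the effects shared by equal replicate numbers. Without BcatGOF replicate 2, r was 0.310, and without wild-type replicate 3 and BcatGOF replicate 2 it was 0.377. Snora15 was the 1 gene called in both comparisons. Inhba (1.84 and 1.94), Gli1 (1.73 and 1.63), Snai1 (0.99 and 1.13) and Skil (0.68 and 0.96) passed in both comparisons adjusted over the list alone, with the log2 fold changes given for wild-type and then BcatGOF coculture. The controls are too few to be divided between the comparisons.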

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

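In this part the tests of a wrong label, of a mixture, of the replicate series, of the epithelial profile and of depth were chosen after the result was seen, and those of enteroid RNA behind the hypoxia list and of other splits before.

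Camera called 16 lists in the contrast of BcatGOF with wild-type coculture, a test of the difference between groups (adjusted p from 4.57e-17 to 0.0492, and adjusted p from 0.504 to 0.713 with an estimated correlation). Of 100 draws of unchanged data 24 gave at least 16 lists, with a median of 13. The next setting leaves BcatGOF replicate 1 alone in its group, so it cannot tell epithelial content from the loss of BcatGOF replicate 2. Without wild-type replicate 3 and BcatGOF replicate 2, 4 of the 16 calls kept their direction and threshold, and 4 turned direction. Median log2 fold changes were -0.601 for cell cycle genes, -0.698 for collagens and cross-linking, -0.482 for TGF-β response genes and -0.246 for ribosomal proteins. They were -0.856 for myofibroblast genes, -0.743 for other matrix glycoproteins, -0.496 for fibroblast activation markers, -0.465 for WNT ligands and R-spondins and -0.346 for canonical WNT targets. On the higher side they were 1.55 for EGF family ligands, 0.602 for epithelial markers, 0.542 for BMP and SMAD targets and 0.486 for FGF, HGF and IGF ligands. They were 0.289 for hypoxia and glycolysis, 0.284 for NRF2 and metallothionein genes and 0.146 for interferon-stimulated genes. Without BcatGOF replicate 1 the medians became -1.02 for cell cycle genes, -1.69 for myofibroblast genes, 3 for EGF family ligands and 1.36 for epithelial markers. They shrank to -0.027 for ribosomal proteins, -0.37 for WNT ligands and R-spondins and 0.044 for interferon-stimulated genes. The other called lists had larger medians in the same direction. That fit sets BcatGOF replicate 2 against wild-type libraries of all numbers. Between libraries of the same number the mean of the ribosomal proteins differed by -0.50 in replicate 1 and -0.20 in replicate 2.

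The BcatGOF libraries lay apart, with Il11 at 85.8 FPKM in replicate 1 and 2587 FPKM in replicate 2. The tables argue against replicate 1 being a mislabelled mesenchyme-only library, since 15 of 18 epithelial markers were above the highest mesenchyme-only library, where a mesenchyme-only library reached at most 8 above the other two. A mixture of coculture and mesenchyme-only RNA in replicate 1 stays open. Genes were taken that were over 4-fold apart between replicates 1 of wild-type coculture and mesenchyme only, with at least 5 FPKM in the higher. They were also over 4-fold apart in the same direction between replicates 2 of BcatGOF coculture and mesenchyme only. BcatGOF replicate 1 lay a median of 0.362 of the way for 41 lower genes (quartiles 0.191 and 0.586) and 0.459 for 17 higher genes (0.256 and 0.592). A mixture predicts similar shares. Genes chosen for distant values in 2 libraries can also place another library between them without a mixture, so the shares do not decide it. A smaller response of the whole replicate 1 series cannot be told apart, since the SD over genes of wild-type coculture minus mesenchyme only was 0.470 in replicate 1 against 0.489 and 0.587 in the others, a margin under their spread, whereas for BcatGOF it was 0.327 and 0.738. Sex, which goes with the replicate number, also stays open and was not tested.

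Epithelial transcripts appeared in sorted stromal cells from all cocultures, with Krt8 at 13.3 ± 19.1 FPKM (n = 3) and 22.9 ± 22.1 FPKM (n = 2) against 0.0688 ± 0.0153 FPKM (n = 3) in cells grown alone. A candidate source is RNA or cells of the enteroids carried through the GFP sort and the removal of dead cells. One source predicts 1 profile. Over the 13 of 18 epithelial markers near 0 in cells grown alone, the lowest correlation between coculture libraries was 0.446 and the highest 0.908. The lowest value lies between the limits set for the test, which therefore does not decide it. Wild-type and mutant enteroids can also differ in the genes they express. Expression of these genes by the stromal cells in coculture was not tested and stays open.

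The hypoxia and glycolysis list was higher in both cocultures, 26 of 26 members in each. Over the mesenchyme-only library of the same number the list's mean rose by 1.21, 0.12 and 0.88 in wild-type replicates 1, 2 and 3. It rose by 0.86 and 1.24 in BcatGOF replicates 1 and 2, so the rise was smallest in wild-type replicate 2. Carried enteroid RNA as the whole cause is argued against: the median member's rise per FPKM of epithelial markers differed 11.7-fold between coculture libraries, from 6.16 in wild-type replicate 1 to 0.527 in wild-type replicate 3, where 1 source predicts a constant ratio. A linear trend with depth as the whole cause is argued against as well: the slope of the list mean on relative depth within groups was -1.82 (SE 2.4), where the rise in wild-type coculture needs -16.2. With relative depth as a covariate the list's median was 0.654 in place of 0.679, and 26 of 26 members stayed higher. A response of the stromal cells to enteroids, or to lower oxygen or nutrients in a droplet that also holds enteroids, was not tested.

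For wild-type coculture against mesenchyme only, 6 samples make 10 splits of 3 against 3, too few for a share under 0.05. Of the 10, 3 splits, the real one included, gave 1 gene, so the real value was 1 and the highest other 1. At least 11 lists were called in 5 splits, the real one included, with 11 in the real split and 22 in the highest other, which set mesenchyme-only replicates 1 and 2 with wild-type replicate 2. That split parts 1 pair of equal numbers, whereas the real one and 3 others part all 3 pairs and these 3 gave 7, 9 and 8 lists with 0, 0 and 1 genes.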

How the results depend on the processing

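Omitting small RNA genes, omitting wild-type replicate 3 with BcatGOF replicate 2, and the block without BcatGOF replicate 1 are alternatives chosen after seeing the data, and all others were planned. Named genes were recomputed under 13 of the alternatives and called lists under 16. Named genes kept their direction and side of the threshold in 2438 checks, newly passed in 26 and reversed in 97, and called lists kept theirs in 537, lost the threshold in 117 and reversed in 13. Camera with an estimated correlation gave 0 lists for BcatGOF coculture against mesenchyme only, 0 for wild-type coculture against mesenchyme only and 0 for BcatGOF against wild-type coculture. It was run only without the replicate block. Scaling changed none of the 3 gene counts, and quantile normalization ended 1 of the 42 list calls. The depth of the libraries is unknown, so how far it limits genes with low values cannot be given. Count models were not run because the tables hold no counts. Where leaving out a library left 1 BcatGOF library, that lone sample is assumed to vary like the other groups. Except where a sentence gives the construction, the cause of a change was not tested.

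The count of changed genes for wild-type coculture against mesenchyme only was 1, and it became 2 with the replicate block, 5 with the replicate block as a random effect, 9 with only the 2 groups compared in the fit and 4 with sample quality weights. It was 9 (1 higher, 8 lower) without wild-type replicate 3 and BcatGOF replicate 2, 36 with the replicate block and without BcatGOF replicate 1, and 0 with the stricter filter of a mean of at least 5 and without small RNA genes, since both remove Snora15. For BcatGOF coculture against mesenchyme only the count was 1, and it became 6 with no filter, 0 with the stricter filter, 0 without small RNA genes, 2 without wild-type replicate 3 and BcatGOF replicate 2, and 340 with the replicate block and without BcatGOF replicate 1. For BcatGOF against wild-type coculture it was 0, and it became 4 with no filter. Leaving out each library in turn gave 1 to 198 genes for BcatGOF coculture against mesenchyme only (2 without wild-type replicate 2) and 1 to 9 for wild-type coculture against mesenchyme only. The replicate block changed no other gene count by over 1.5 times.

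Called lists for BcatGOF against wild-type coculture numbered 16, from 8 to 20 without single libraries, and 7 without wild-type replicate 3 and BcatGOF replicate 2. Without that pair the mean log2 fold change over a list turned to -0.25 for BMP and SMAD targets, -0.16 for hypoxia and glycolysis and 0.11 for myofibroblast genes. For EGF family ligands it was 0.022 with the test's direction turned down, and for oxidative phosphorylation in BcatGOF coculture against mesenchyme only it was -0.10. With the replicate block and without BcatGOF replicate 1 the interferon list of BcatGOF against wild-type coculture turned to -0.090. Without single libraries the mean ran from -0.10 to 0.48 for oxidative phosphorylation in BcatGOF coculture against mesenchyme only. For BcatGOF against wild-type coculture it ran from -0.023 to 0.28 for interferon-stimulated genes, -0.074 to 1.06 for BMP and SMAD targets, -0.79 to 0.040 for canonical WNT targets, -0.23 to 0.84 for hypoxia and glycolysis and -1.72 to 0.026 for myofibroblast genes. Of the 42 list calls, 36 to 39 kept direction and threshold without single mesenchyme-only or wild-type libraries, 35 without BcatGOF replicate 1 and 23 without BcatGOF replicate 2. The replicate block ended 4 of the 42 list calls, for mesothelial markers, oxidative phosphorylation, other matrix glycoproteins and WNT ligands. It gained 6 in camera. For BcatGOF coculture against mesenchyme only this was ribosomal proteins (adjusted p = 3.89e-06). For wild-type coculture against mesenchyme only these were ribosomal proteins (0.00447), YAP/TAZ targets (0.0263) and NRF2 genes (0.0489). For BcatGOF against wild-type coculture these were cholesterol biosynthesis (7.59e-06) and NF-κB response genes (0.0428). With an estimated correlation and no block, camera gave these 6 adjusted p-values from 0.581 to 0.883. The correlation between the coculture effects was 0.661, and it was 0.377 without wild-type replicate 3 and BcatGOF replicate 2 and 0.31 to 0.741 without single libraries.

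Single genes turned direction as follows. With a pseudocount of 0.1, Foxl1 was at -0.11 for BcatGOF against wild-type coculture. With quantile normalization, log2 fold changes were Fdps -0.017 for BcatGOF coculture against mesenchyme only, Cd81 -0.0052 for wild-type coculture against mesenchyme only and Foxl1 -0.021 for BcatGOF against wild-type coculture. With the replicate block they were Id3 -0.032, Fdps -0.26, Saa3 -0.35, Smoc2 0.23 and Cebpb 0.032 for BcatGOF coculture against mesenchyme only and Rspo3 0.0024, Foxl1 -0.048, Tgfb2 0.068, Gli1 0.0018 and Ccnd1 -0.0030 for BcatGOF against wild-type coculture. With sample quality weights they were Smoc2 0.40, Cebpb 0.45 and Junb 0.096 for BcatGOF coculture against mesenchyme only, Col3a1 0.14, Ier3 0.29 and Ifi27 0.014 for wild-type coculture against mesenchyme only and Foxl1 -0.0052 for BcatGOF against wild-type coculture. Without single libraries, log2 fold changes for BcatGOF coculture against mesenchyme only ran for Id3 from -0.59 to 0.81, Saa3 from -0.74 to 0.92, Pcna from -0.39 to 0.16, Cebpb from -0.78 to 0.72, Fdps from -0.39 to 0.48, Smoc2 from -0.73 to 0.60, Cox6a1 from -0.36 to 0.66, Cox6b1 from -0.19 to 0.56, Cd81 from -0.20 to 0.44, Grem1 from -0.99 to 0.19, Tgfb2 from -1.57 to 0.19, Serpina3n from -4.91 to 0.60, Chl1 from -3.43 to 0.52, Mki67 from -1.43 to 0.31, Id1 from -0.38 to 1.87, Mcm7 from -0.74 to 0.029, Lcn2 from -1.18 to 3.69 and Dcn from -0.13 to 0.93. For wild-type coculture against mesenchyme only they ran for Cd81 from -0.029 to 0.15, Cebpb from -0.15 to 0.45, Ier3 from -0.38 to 0.36, Col3a1 from -0.39 to 0.32 and Ifi27 from -0.36 to 0.020. For BcatGOF against wild-type coculture they ran for Cd81 from -0.29 to 0.35, Gli1 from -0.45 to 0.26, Rspo3 from -0.47 to 0.19, Tgfb2 from -0.93 to 0.83, Ctnnb1 from -0.14 to 0.16, Ccnd1 from -0.49 to 0.72, B2m from -0.37 to 0.12, Ifi27 from -0.26 to 0.12, Foxl1 from -0.50 to 0.51, Grem1 from -0.36 to 0.82, Wnt2b from -0.37 to 1.13, Mt1 from -0.24 to 0.76, Spon2 from -1.09 to 0.61, Pdgfra from -0.82 to 0.094, Tgfb1 from -0.29 to 0.78, Acta2 from -3.41 to 0.61, Id3 from -0.28 to 1.12, Id1 from -0.30 to 1.95, Vegfa from -0.19 to 1.19, Igf1 from -2.0 to 0.40, Prdx1 from -0.050 to 0.63, Il11 from -0.89 to 4.01, Col3a1 from -1.94 to 0.16, Gapdh from -0.57 to 1.02, Aldoa from -0.32 to 0.91 and Dcn from -0.23 to 0.83.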

Other observations

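In this part the tests on the authors' deposited table and on ratios of Snora15 between libraries were chosen after the result was seen, and the test of small RNA dropout before.

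Inflammatory cytokines and chemokines were higher in BcatGOF coculture than in cells grown alone for 19 of 27 members, with a median of 0.91 that did not pass (adjusted p = 0.0739 in camera, and adjusted p = 0.744 with an estimated correlation). Without BcatGOF replicate 1 the median was 1.55 and the list passed (adjusted p = 0.00830). They were higher for 18 of 27 in wild-type coculture, with a median of 0.28 (adjusted p = 0.772). Il11, a member of the IL-6 family, was at 207 ± 188 FPKM (SD, n = 3) in wild-type coculture and at 85.8 and 2587 FPKM in the BcatGOF cocultures, against 20.5 ± 17 FPKM (n = 3) in cells grown alone. Ribosomal protein genes were higher in wild-type coculture than in cells grown alone for 34 of 34 members, by a median of 0.15 that did not pass (adjusted p = 0.0529, adjusted p = 0.883 with an estimated correlation, and 0.00447 with the replicate block). The mean difference between libraries of the same number was 0.41, -0.23 and 0.26 in replicates 1, 2 and 3. In BcatGOF coculture 31 of 34 were lower than in cells grown alone, by a median of -0.10 (adjusted p = 0.0930, adjusted p = 0.754 with an estimated correlation, and 3.89e-06 with the replicate block). Without BcatGOF replicate 1 the median was 0.12, with BcatGOF replicate 2 set against mesenchyme-only libraries of all numbers. Between libraries of the same number the list mean was lower in both, by -0.092 in replicate 1 and -0.43 in replicate 2. Basement membrane genes had a median of -0.32 in BcatGOF coculture (adjusted p = 0.105) and 0.036 in wild-type coculture (adjusted p = 0.902) against cells grown alone. Without BcatGOF replicate 1 the median was -0.95 in BcatGOF coculture against cells grown alone. Against wild-type coculture it went from -0.20 (adjusted p = 0.0542 in camera) to -1.01. With all libraries and an estimated correlation, camera gave an adjusted p of 0.744 against cells grown alone and 0.713 against wild-type coculture. BMP ligands had medians of -0.37 (adjusted p = 0.0829) and -0.40 (adjusted p = 0.395), and Bmp4 was at 14.5 ± 2.34 FPKM in BcatGOF coculture, 19.1 ± 5.69 FPKM in wild-type coculture and 26.2 ± 1.1 FPKM in cells grown alone. TGF-β response genes, higher in wild-type coculture, had a median of 0.046 and a mean of -0.071 with the test's direction up in BcatGOF coculture (adjusted p = 0.387).

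Smooth muscle and pericyte markers did not pass, with medians of -0.86 in BcatGOF coculture (adjusted p = 0.168) and -0.40 in wild-type coculture (adjusted p = 0.902) against cells grown alone. The 3 tested glial and neuronal markers had medians of 1.07 (adjusted p = 0.464) and 0.87 (adjusted p = 0.286). Notch genes had medians of 0.058 (adjusted p = 0.464) and 0.16 (adjusted p = 0.820), and p53 and senescence genes medians of 0.13 (adjusted p = 0.375) and 0.11 (adjusted p = 0.902). Pdgfra, by which the cells were chosen, was at 109 ± 22.1 FPKM in cells grown alone, 93.9 ± 12.5 FPKM in wild-type coculture and 76.1 ± 33.5 FPKM in BcatGOF coculture.

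A candidate explanation for the fold changes in the authors' deposited table is that the deposited comparison was computed without BcatGOF replicate 1. The fold changes in the authors' deposited table lay within 0.5 log2 of replicate 2 alone for 86.9% of 1900 genes and of the mean of both libraries for 24.2%, where a fit of both libraries predicts the reverse. In sign, replicate 2 was the same as the authors' deposited table for 100% of the genes and replicate 1 for 59.5%. Whether the deposited comparison without replicate 1 gives the 2184 genes of the authors' deposited table was not tested, because count models were not run. The design of that comparison is not given in the sources used here.

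The libraries came from poly-A RNA sequencing, and whether reads at Snora15 come from the small nucleolar RNA itself was not tested. Snora15 was listed at 0 in all 5 cocultures. That it rests on few reads stays open: its depth-scaled values in mesenchyme only 2 and 3 were 0.748 and 0.737 of that in replicate 1, which ratios of small whole numbers can also give. Chance dropout also stays open, since of 46 genes taken as small RNA genes by symbol and above 0 in exactly 3 libraries, spread over the 56 ways to choose 3 of 8, 0.821 are expected in the mesenchyme-only libraries alone and 2 were found.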
